A study of Mus musculus with 24 samples.

How the data were processed

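The series measured gene expression on 24 oligonucleotide arrays. The RNA came from tubules microdissected from the left kidneys of male C57BL/6J mice after collagenase treatment. Each array carried 1 pool of RNA from 1 tubule segment at 1 time of day. The segments were the distal convoluted and connecting tubules together (DCT/CNT) and the cortical collecting ducts (CCD). Mice were kept in 12 h of light and 12 h of darkness and were killed every 4 h, at 6 zeitgeber times counted from lights on (ZT0). Per the labels, 2 pools per segment and time were hybridized, with equal amounts of RNA from 5 animals per time, and 10 ng of total RNA was amplified for each array. The labels do not state whether the 2 pools of a time hold RNA of the same animals, nor whether the segments were taken from the same animals.

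The authors' deposited table holds RMA values on the log2 scale for 45101 probe sets, without a stated software version. The labels do not state whether the arrays of both segments were normalised in 1 run. Values were used as deposited, with no filter on dim genes and no batch term, since the labels give no batch or date. Probe sets were joined to gene symbols through the platform's probe table. Of all probe sets, 34958 named 1 gene symbol, 932 named several and 9211 named none. Of those with 1 symbol, 34754 matched the reference gene table (assembly GRCm38.p6) by gene number, and 0 symbols needed updating. For each of the 18194 genes the probe set with the highest mean over all arrays was kept. More than 1 probe set was available for 9012 genes. Arrays have no read depth, and their number limits the precision.

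A 24 h cosinor model (cosine and sine terms of time) was fitted to both segments together with limma 3.58.1 in R 4.3.3, with a separate mean, cosine and sine for each segment and 1 residual variance per gene (18 residual degrees of freedom). Rhythm in a segment was tested with the moderated F test on its cosine and sine terms, and the rhythm difference with the F test on the 2 differences of these terms. Amplitude is the distance from the fitted mean to the fitted peak in log2 units, and peak time is the fitted maximum. The segment difference was the mean of the 6 DCT/CNT group means minus the mean of the 6 CCD group means, with limma's moderated test. P-values were adjusted with the Benjamini-Hochberg method over all genes and called at adjusted p under 0.05. All standard errors (SE) are those of limma's moderated fit, and standard deviations (SD) are between pools. P-values therefore measure the spread between pools, not between animals.

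These tests, the rule for named genes and 25 gene lists were chosen before the data were examined. Named genes were, per segment, all genes of the core clock and clock output lists and the 20 genes with the largest amplitudes among the called ones whose 2 pools at the highest time both exceeded the 2 pools at the lowest time. For the segment difference they were the 15 largest differences each way among called genes with no overlap of the 12 against 12 arrays. For the rhythm difference they were up to 10 genes with the smallest adjusted p. From every other list they were up to 4 members with the smallest adjusted p. Ranked choices left out predicted genes without a stated function and olfactory and vomeronasal receptors. The lists cover the core clock, clock output, DCT and CNT markers, principal cell sodium and potassium transport, water transport and vasopressin response, intercalated cells, proximal tubule, thick ascending limb, podocytes, endothelial cells, vascular smooth muscle with mesangium and fibroblasts, leukocytes, erythrocytes, immediate early response, heat shock, cold-inducible RNA-binding proteins, glucocorticoid response, S phase, mitosis, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, unfolded protein response, xenobiotic and PAR bZIP targets, and ribosomal proteins. Lists share members, such as Tsc22d3 and Usp2 in the clock output and principal cell lists. Some list genes were not analysed here.

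Lists were tested with camera, with a preset inter-gene correlation of 0.01 and again with the correlation estimated, adjusted over the lists within a contrast. The contrasts were the sine term (light-phase middle against dark-phase middle) and the cosine term (lights on against lights off) in each segment, and DCT/CNT minus CCD. The cold-inducible list has 1 measured gene and was not tested with camera. A list can lean on both terms of a segment, and for some lists only 1 of these leans is given below.

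The median gene differed between the segments by -0.13 log2 units in the deposited values, and by 0.08, 0.03 and 0.03 after the arrays were brought to equal medians, quantile normalised or cyclic loess normalised. The medians made equal were those over the 18194 genes, while array medians given in the report are over all probe sets. Segment differences of named genes are therefore given relative to the median gene, and their adjusted p-values belong to the difference in the deposited values.

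The fits were tested on simulated data of the same size with known rhythms. The simulated genes had independent normal noise, and 66 or 67 genes were changed per amplitude in each segment. Real genes are correlated and many more differ between the segments, so the percentages hold for the simulated setting only. At amplitudes of 0.25, 0.5 and 1 the rhythm test recovered 28.4%, 85.1% and 97.0% of rhythmic genes in DCT/CNT and 26.9%, 80.6% and 100.0% in CCD, and the test of the rhythm difference recovered 9.7%, 62.7% and 94.7%. False calls made up 6.0%, 4.8% and 3.5% of these calls. At log2 differences of 0.25, 0.5 and 1 the segment test recovered 20.9%, 86.6% and 98.5%, with 2.1% false calls.

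Alternatives covered a pool block, a random block for same-number pools of the segments, pairing by pool number, the 3 rescalings, a filter on the lower 50% of mean values, the mean of all probe sets per gene, empirical Bayes with trend and robust options, array weights, thresholds of 0.1 and 0.01, separate fits per segment, an F test over group means, an added 12 h component, the proximal tubule list mean as a covariate, and leaving out each array or each time. Covariates for the proximal tubule and thick ascending limb lists together, and the gene lists after quantile normalisation, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.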

Results

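Expression was measured on 24 arrays in 12 groups, formed by 2 tubule segments and 6 zeitgeber times with 2 pools in each group. Over all probe sets, the deposited log2 values had a mean array median of 5.86 (SD 0.027, n = 12) in DCT/CNT and 5.85 (SD 0.012, n = 12) in CCD. The interquartile range of values was narrower on DCT/CNT arrays (mean 3.49, SD 0.113, n = 12) than on CCD arrays (mean 4.20, SD 0.072, n = 12). The 2 pools of a group correlated across genes with r from 0.988 to 0.995, and genes are not independent replicates. The comparisons ask which transcripts follow the time of day in each segment, whether they do so differently, and which transcripts differ between the segments.

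In DCT/CNT core clock and clock output genes made up 5 of the 6 largest amplitudes among called genes, with Sphk2, described below, as the other. Dbp, a PAR bZIP transcription factor driven by the clock, swung 27.3-fold between trough and peak (amplitude 2.39, SE 0.13) and peaked at ZT 10.5, shortly before lights off (adjusted p = 7.01e-10). Arntl, which encodes the clock activator BMAL1, swung 10.7-fold (amplitude 1.71, SE 0.13) and peaked at ZT 0.871, close to lights on (adjusted p = 1.24e-07). Npas2, whose product partners BMAL1, swung 11.5-fold (amplitude 1.76, SE 0.18) with a peak at ZT 1.89. The repressors followed in sequence, with Nr1d1 at its peak at ZT 8.31 (10.2-fold), Per3 at ZT 13.1 (6.01-fold), Per2 at ZT 15.6 (5.71-fold) and Cry1 at ZT 19.7 (6.27-fold).

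Of the core clock list, 12 of 16 measured genes were called rhythmic in DCT/CNT, and 12 were called when adjusted over the list alone. Clock, Cry2 and Nr1d2 were called with amplitudes of 0.55, 0.57 and 1.72 (SE 0.06, 0.08 and 0.14). Per1, Rora and Ciart were called with amplitudes of 0.49, 0.30 and 0.42, but lost the call in 4, 4 and 6 of the 24 omissions of 1 array, with adjusted p up to 0.0724, 0.115 and 0.104. Bhlhe40, Bhlhe41, Csnk1d and Csnk1e were not called, with adjusted p of 0.474, 0.798, 0.857 and 0.817. All 12 measured clock output genes were called, and 12 when adjusted over the list alone. Among them Tef swung 3.71-fold (peak ZT 13.1), Hlf 2.87-fold (peak ZT 14.5), Nfil3 5.13-fold (peak ZT 22.3), Tfrc, the transferrin receptor, 3.47-fold (peak ZT 22.8) and Nampt, an enzyme of NAD synthesis, 1.90-fold (peak ZT 17.1). Wee1 was called with an amplitude of 0.36 and lost the call in 5 of the 24 omissions, with adjusted p up to 0.111. The output list as a whole leaned towards the dark phase (camera adjusted p = 0.000125; adjusted p = 0.224 with an estimated correlation).

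**Figure D1:**
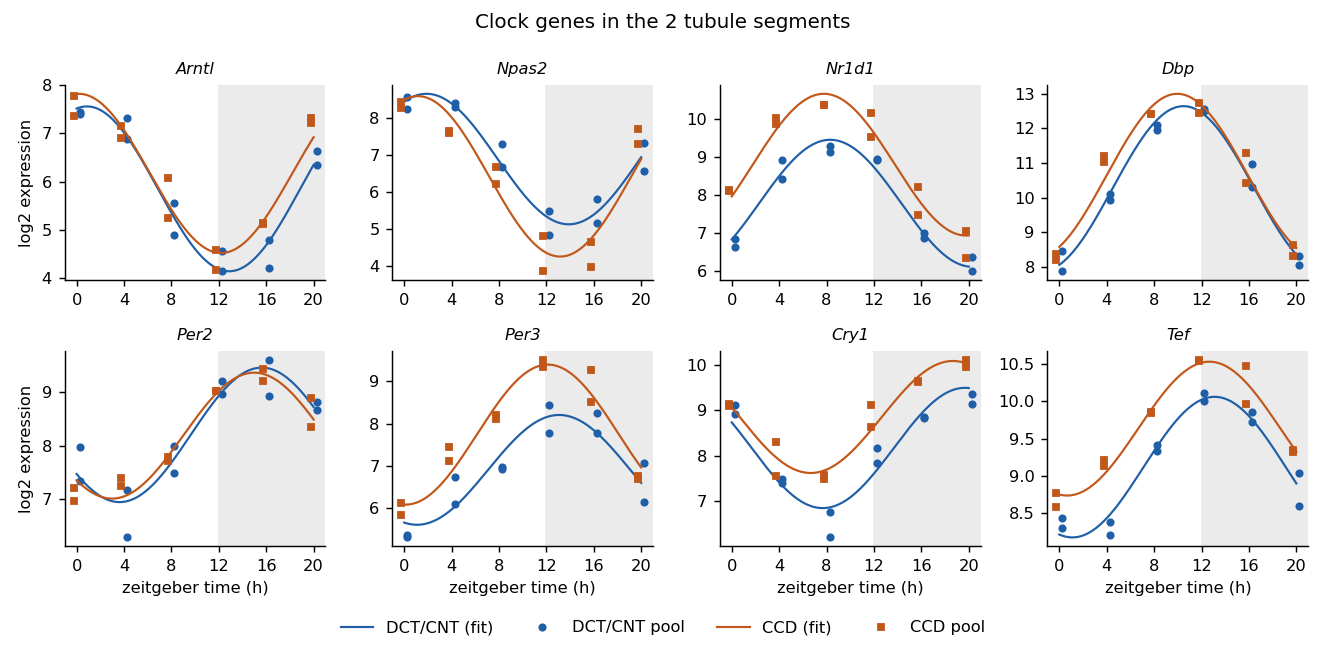
Log2 expression of 8 clock genes against zeitgeber time in hours, with 1 point per pool (2 per segment and time), the fitted 24 h curves as lines and the dark phase shaded. Arntl and Npas2 peak near lights on and Dbp peaks near ZT 10.5 in DCT/CNT and ZT 9.95 in CCD.

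Genes of salt, water and calcium handling were called as well. In DCT/CNT the vasopressin receptor genes Avpr1a (amplitude 0.62, SE 0.07, 2.35-fold, peak ZT 0.155, adjusted p = 0.000129) and Avpr2 (amplitude 0.40, SE 0.05, 1.74-fold, peak ZT 21.5, adjusted p = 0.000152) peaked at lights on and late in the dark phase. Slc8a1, the sodium-calcium exchanger, swung 2.05-fold (amplitude 0.52, SE 0.11, peak ZT 23.1, adjusted p = 0.015). Kcnj1, the potassium channel ROMK, swung 1.30-fold (amplitude 0.19, SE 0.04, peak ZT 20.5, adjusted p = 0.00757). Kl, which encodes Klotho, and the kinase gene Wnk4 were called with amplitudes of 0.25 and 0.23, and each lost the call in 5 of the 24 omissions of 1 array, with adjusted p up to 0.0909 and 0.0908. Slc8a1 lost the call without ZT0, ZT12 or ZT20 (adjusted p up to 0.148) and Kcnj1 without ZT8 (adjusted p = 0.132), while Avpr1a and Avpr2 kept it in all 24 omissions of 1 array and all 6 of 1 time. The sodium channel subunit gene Scnn1a had an amplitude of 0.19 (SE 0.05) and did not pass the test (adjusted p = 0.0701).

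Among DCT and CNT markers, 7 of 19 were called, 9 when adjusted over the list alone, and none of the 7 peaked in the light phase. The list leaned towards lights on (adjusted p = 0.00463, and 0.474 with an estimated correlation) and the dark phase (adjusted p = 0.0301, and 0.533 with an estimated correlation). The mean of this list was 10.66 (SD 0.079, n = 2) at ZT8 and 11.27 (SD 0.016, n = 2) at ZT20, and its 2 pools differed most at ZT16 (SD 0.582). The thick ascending limb list was lowest at ZT8 as well, with 6.98 (SD 0.122, n = 2) at ZT8, 7.48 (SD 0.402, n = 2) at ZT20 and the same pool lower at ZT16 (SD 0.707), so a varying make-up of the pools was not separated from the course of the marker list. The sodium-chloride cotransporter gene Slc12a3, the classic DCT marker, had an amplitude of 0.13 (SE 0.39, adjusted p = 0.967). In the principal cell list 3 of 17 were called (5 adjusted over the list alone), namely Kcnj1 and the clock output genes Usp2 and Tsc22d3. In the water transport list 3 of 19 were called (5 adjusted over the list alone). In the intercalated cell list 4 of 19 were called (8 adjusted over the list alone), all with peaks in the light phase, among them Kit (amplitude 0.34, SE 0.06, peak ZT 5.26), which lost the call without ZT8 or ZT16 (adjusted p up to 0.0715). That list leaned towards the light phase (adjusted p = 0.00035; adjusted p = 0.261 with an estimated correlation).

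**Figure D2:**
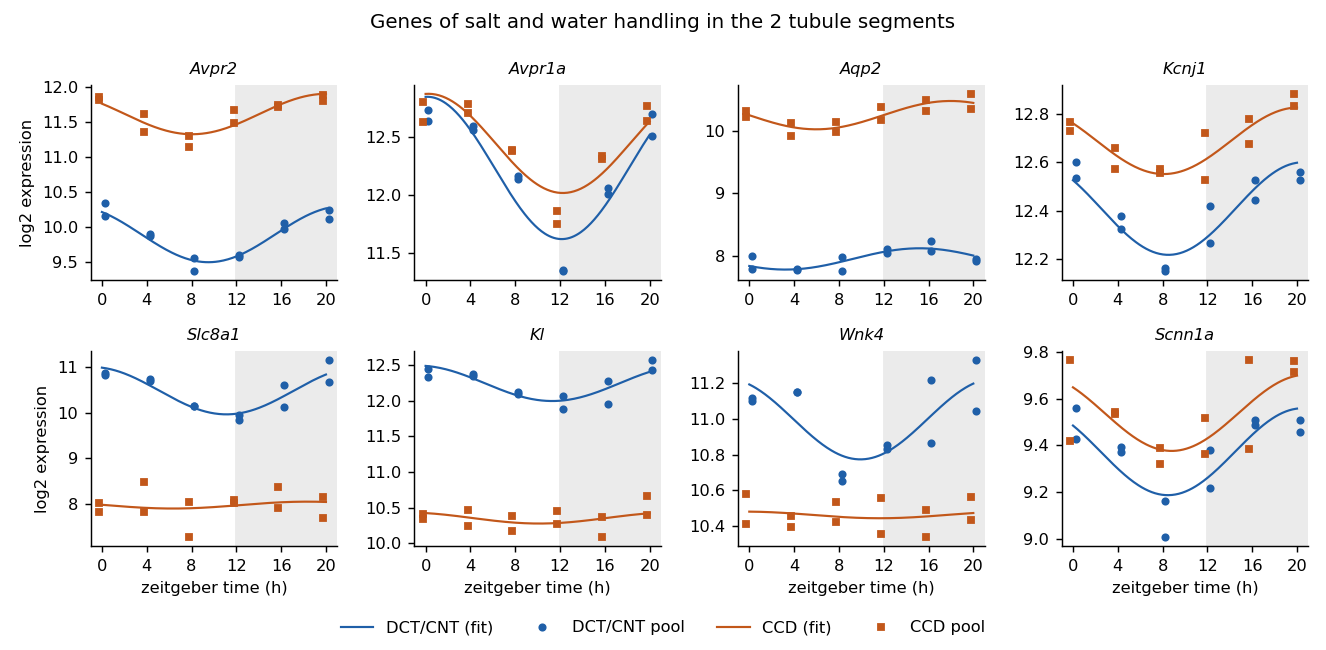
Log2 expression of 8 genes of salt, water and calcium handling against zeitgeber time in hours, with 1 point per pool (2 per segment and time) and the fitted 24 h curves as lines. Avpr2 and Aqp2 lie higher in CCD and Slc8a1 and Kl higher in DCT/CNT at every time.

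Called stress and secretory pathway genes in DCT/CNT peaked in different parts of the day, without a test between the lists. Of the immediate early response list 7 of 20 were called (12 adjusted over the list alone), all with peaks in the light phase, such as Nr4a1 (amplitude 0.66, SE 0.11, peak ZT 4.48) and Fos (amplitude 0.31, SE 0.07, peak ZT 3.26). This list leaned towards the light phase (adjusted p = 4.64e-07; adjusted p = 0.292 with an estimated correlation). Of the heat shock list 5 of 19 were called (9 adjusted over the list alone), none with a peak in the light phase, such as Hsph1 (amplitude 0.42, SE 0.07, peak ZT 17.7) and Hspa5, an endoplasmic reticulum chaperone also in the unfolded protein response list (amplitude 0.47, SE 0.07, peak ZT 20.8). It leaned towards the dark phase (adjusted p = 4.64e-07; adjusted p = 0.306 with an estimated correlation). Of the unfolded protein response list 9 of 20 were called (14 adjusted over the list alone), none with a peak in the light phase, with Sdf2l1 (amplitude 0.82, SE 0.13, peak ZT 21.6), Manf (amplitude 0.64, SE 0.12, peak ZT 20.2) and Herpud1 (amplitude 0.46, SE 0.07). That list leaned towards lights on (adjusted p = 6.27e-07; adjusted p = 0.335 with an estimated correlation) and the dark phase (adjusted p = 4.37e-05; adjusted p = 0.34 with an estimated correlation). Cirbp, a cold-inducible RNA-binding protein gene and the 1 measured member of its list, peaked at ZT 7.47 (amplitude 0.76, SE 0.13, adjusted p = 0.00464). Nr4a1 lost the call without ZT4 (adjusted p = 0.0679), Manf without ZT8 (adjusted p = 0.087) and Fos without ZT0, ZT12 or ZT20 (adjusted p up to 0.0839).

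Metabolic groups followed in DCT/CNT. Of the cholesterol synthesis list 7 of 14 were called (8 adjusted over the list alone), among them Insig1 (amplitude 0.43, SE 0.08, peak ZT 2.79), Fdps (amplitude 0.42, SE 0.08, peak ZT 1.96) and Nsdhl (amplitude 0.41, SE 0.08, peak ZT 4.36). The list leaned towards lights on (adjusted p = 5.66e-06; adjusted p = 0.0711 with an estimated correlation). Of the glucocorticoid response list 9 of 18 were called (10 adjusted over the list alone), such as Zbtb16 (amplitude 1.02, SE 0.19, peak ZT 11.5), Pdk4 (amplitude 0.71, SE 0.12, peak ZT 4.21) and Mt2 (amplitude 0.60, SE 0.11, peak ZT 11.4). It leaned towards lights off (adjusted p = 6.52e-05; adjusted p = 0.0767 with an estimated correlation). Of the xenobiotic and PAR bZIP target list 6 of 17 were called (8 adjusted over the list alone), none with a peak in the light phase, and it leaned towards the dark phase (adjusted p = 0.00404; adjusted p = 0.261 with an estimated correlation). Its mean was lowest at ZT8 (6.78, SD 0.086, n = 2) and highest at ZT12 (7.37, SD 0.015, n = 2), the same times as for the proximal tubule markers given below, so the 2 courses were not separated. Of the fatty acid oxidation list 2 of 20 were called (4 adjusted over the list alone), namely Acot2 (amplitude 0.32, SE 0.05, peak ZT 4.97) and Acaa2 (amplitude 0.23, SE 0.04, peak ZT 10.7). Each of these 8 named genes lost the call without 1 to 3 of the 6 times, with adjusted p up to 0.0944 for Insig1, 0.0861 for Fdps, 0.115 for Nsdhl, 0.15 for Zbtb16, 0.0533 for Pdk4, 0.0757 for Mt2, 0.0642 for Acot2 and 0.0736 for Acaa2.

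Markers of other cell types also varied between the DCT/CNT pools. The proximal tubule list mean was 7.12 (SD 0.037, n = 2) at ZT8 and 8.53 (SD 0.010, n = 2) at ZT12. In this list 1 of 19 genes was called, Pck1, an enzyme of gluconeogenesis (amplitude 1.10, SE 0.26, peak ZT 15.2, adjusted p = 0.0321; 2 adjusted over the list alone), and Pck1 lost the call in 4 of the 24 omissions of 1 array, with adjusted p up to 0.0643. The list leaned towards the dark phase (adjusted p = 0.000643, and 0.517 with an estimated correlation) and lights off (adjusted p = 0.00172, and 0.545 with an estimated correlation). The podocyte list had 1 of 7 called and the leukocyte list 1 of 15. The thick ascending limb, endothelial, vascular and erythrocyte lists had 0 called by limma of 10, 12, 13 and 5, with unadjusted p under 0.05 in 1, 2, 3 and 1. Oxidative phosphorylation had 0 called of 33 (1 at unadjusted p under 0.05), ribosomal proteins 1 of 24, S phase 2 of 20 and mitosis 1 of 19. The vascular list leaned towards the dark phase (adjusted p = 0.0294; adjusted p = 0.389 with an estimated correlation), oxidative phosphorylation towards lights on (adjusted p = 0.0119; adjusted p = 0.494 with an estimated correlation) and ribosomal proteins towards the light phase (adjusted p = 0.0446; adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone, the called counts of the podocyte, leukocyte, erythrocyte, S phase and mitosis lists were 2, 2, 1, 2 and 1.

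Across all genes, 1195 of 18194 (6.57%) were called rhythmic in DCT/CNT, and in 1194 of them both pools at the highest time exceeded both pools at the lowest. These times were picked from the same values, and the uncalled genes Bhlhe40, Bhlhe41, Csnk1d and Csnk1e met this too. It is therefore no separate support for the calls. The median amplitude of the called genes was 0.30, and 143 swung more than 2-fold. Peaks were most frequent between ZT4 and ZT8 (329 genes, 27.5%). Outside the clock lists the largest amplitudes belonged to Sphk2 (2.21, SE 0.09), a sphingosine kinase gene, Tspyl3 (1.36, SE 0.29), Ugt2b34 (1.31, SE 0.32), Pck1 (1.10, SE 0.26), Ranbp3l (1.10, SE 0.14), Ak4 (1.07, SE 0.20), Keg1 (1.06, SE 0.27), Zbtb16 (1.02, SE 0.19), Rnf125 (0.98, SE 0.18) and Grem1 (0.98, SE 0.18). A second Sphk2 probe set had an amplitude of 0.16 (SE 0.09), and Ugt2b34 and Keg1 lost the call in 6 and 15 of the 24 omissions of 1 array, with adjusted p up to 0.106 and 0.111. Tspyl3 lost it without ZT4, ZT16 or ZT20 (adjusted p up to 0.104), Rnf125 without ZT0 (adjusted p = 0.063) and Grem1 without ZT20 (adjusted p = 0.078). The main fit gives both segments 1 variance per gene, while the median SD between pools was 0.186 in DCT/CNT and 0.157 in CCD. The DCT/CNT count was 226 with DCT/CNT fitted alone, below the 456 of CCD fitted alone, so the order of the segments turned. It was 450 with the F test over group means. With array weights it was 788, against 846 in CCD, so the order turned there too. It was between 565 and 788 when 1 of the 6 times was left out, and 663 with proximal tubule and thick ascending limb covariates, an alternative added after the data were seen.

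In CCD core clock and clock output genes made up 6 of the 7 largest amplitudes, again with Sphk2 as the other. Dbp swung 27.0-fold (amplitude 2.38, SE 0.13, peak ZT 9.95, adjusted p = 7.53e-10), Npas2 20.2-fold (amplitude 2.17, SE 0.18, peak ZT 1.17, adjusted p = 9.86e-07), Nr1d1 13.3-fold (amplitude 1.87, SE 0.12, peak ZT 7.77, adjusted p = 1.37e-08) and Arntl 9.88-fold (amplitude 1.65, SE 0.13, peak ZT 0.2, adjusted p = 2.42e-07). Per3 swung 9.83-fold with its peak at ZT 12.1, and Cry1 5.52-fold with its peak at ZT 18.7. Of the core clock list 11 of 16 were called (11 adjusted over the list alone), and of the clock output list 11 of 12 (12 adjusted over the list alone). Per1 and Ciart lost the CCD call in 4 and 5 of the 24 omissions of 1 array, with adjusted p up to 0.07874 and 0.08055. Both lists leaned towards lights off, with adjusted p of 0.000255 and 3.95e-05, and both held with adjusted p = 0.0429 with an estimated correlation. Rora (amplitude 0.14, adjusted p = 0.61) and Hlf (amplitude 0.51, adjusted p = 0.0663) did not pass in CCD, and neither did the differences of their rhythms between the segments (adjusted p = 0.51 and 0.604).

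Outside the clock lists, CCD amplitudes were largest for Sphk2 (2.23, SE 0.09), Rasl11a (1.39, SE 0.18, peak ZT 0.0949), Zbtb16 (1.29, SE 0.19, peak ZT 11.9), St6galnac3 (1.15, SE 0.21, peak ZT 3.03), Trim75 (1.04, SE 0.18, peak ZT 7.85) and Pcp4 (1.02, SE 0.10, peak ZT 8.72). Avpr1a and Avpr2 were called in CCD as well, with amplitudes of 0.43 (SE 0.07, peak ZT 0.25, adjusted p = 0.00661) and 0.29 (SE 0.05, peak ZT 20, adjusted p = 0.00639). Aqp2, the vasopressin-regulated water channel of the collecting duct, had an amplitude of 0.23 (SE 0.05, peak ZT 18.0, adjusted p = 0.0282). It lost the call in 4 of the 24 omissions of 1 array, with adjusted p up to 0.092 (without CCD ZT4 replicate 2, ZT8 replicate 1, ZT16 replicate 2 or ZT20 replicate 2), and in each of the 6 omissions of 1 time (adjusted p up to 0.206). Without ZT8 Avpr2 and Trim75 lost the call (adjusted p = 0.186 and 0.115), without ZT4 Avpr1a (adjusted p = 0.0568), without ZT0 or ZT12 Zbtb16 (adjusted p up to 0.0762), and without ZT0, ZT4, ZT8 or ZT12 St6galnac3 (adjusted p up to 0.115). Scnn1a did not pass (amplitude 0.16, adjusted p = 0.215).

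In CCD, 3 of 17 principal cell, 3 of 19 water transport, 3 of 19 intercalated cell and 1 of 19 DCT and CNT marker genes were called, and 4, 7, 6 and 2 when adjusted over the list alone. The principal cell list leaned towards lights off (adjusted p = 0.0355; adjusted p = 0.404 with an estimated correlation) and the intercalated cell list towards the light phase (adjusted p = 0.0427; adjusted p = 0.447 with an estimated correlation). Of the immediate early response list 7 of 20 were called (11 adjusted over the list alone), 6 of them with peaks in the light phase, such as Nr4a1 (amplitude 0.59, SE 0.11, peak ZT 3.72), which lost the call without CCD ZT4 replicate 2 (adjusted p = 0.0518) and without ZT4 or ZT16 (adjusted p up to 0.221). The list leaned towards the light phase (adjusted p = 2.99e-08, and 0.242 with an estimated correlation) and lights on (adjusted p = 0.000405, and 0.465 with an estimated correlation). Its 2 pools at CCD ZT4 lay at 9.97 and 10.78 (SD 0.572), while its CCD group means ranged from 9.77 at ZT20 to 10.45 at ZT0. The heat shock list had 2 of 19 called (5 adjusted over the list alone) and the unfolded protein response list 4 of 20 (11 adjusted over the list alone), with Herpud1 at an amplitude of 0.47 (SE 0.07, peak ZT 13.3). Both leaned towards the dark phase, with adjusted p of 7.79e-11 and 2.39e-09, and adjusted p = 0.242 with an estimated correlation for each. The cholesterol synthesis list leaned towards lights on (adjusted p = 3.95e-05; adjusted p = 0.0429 with an estimated correlation), with 1 of 14 called, Insig1 (2 adjusted over the list alone). Insig1 had an amplitude of 0.40 (SE 0.08, peak ZT 2.99) and lost the call without CCD ZT16 replicate 1 (adjusted p = 0.081) and without ZT0, ZT12, ZT16 or ZT20 (adjusted p up to 0.181).

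The glucocorticoid response list had 4 of 18 called in CCD (10 adjusted over the list alone) and leaned towards lights off (adjusted p = 0.000218; adjusted p = 0.0631 with an estimated correlation). Fatty acid oxidation had 2 of 20 called (8 adjusted over the list alone), the xenobiotic list 1 of 17 (4 adjusted over the list alone), the podocyte list 1 of 7 and the cold-inducible list 1 of 1. That 1 gene, Cirbp, lost the CCD call in 4 of the 24 omissions of 1 array (adjusted p up to 0.0596). It also lost the call in 4 of the 6 omissions of 1 time (adjusted p up to 0.223). No member was called by limma in the proximal tubule, thick ascending limb, endothelial, vascular, leukocyte, erythrocyte, S phase, mitosis, oxidative phosphorylation and ribosomal protein lists, with unadjusted p under 0.05 in 2, 1, 3, 3, 1, 0, 2, 1, 7 and 3 members. Oxidative phosphorylation and endothelial genes leaned towards lights on (adjusted p = 0.000103 and 0.000651; adjusted p = 0.282 and 0.255 with an estimated correlation), and fatty acid oxidation and ribosomal protein genes towards the light phase (adjusted p = 0.000579 and 0.000161; adjusted p = 0.242 with an estimated correlation for each). The proximal tubule list leaned towards lights off (adjusted p = 0.0169, and 0.573 with an estimated correlation) and the dark phase (adjusted p = 0.0132, and 0.629 with an estimated correlation). Its mean ranged from 7.08 to 8.57 over the CCD arrays, with an SD between the 2 pools of 0.685 at ZT12 and 0.871 at ZT8. Across all genes, 449 (2.47%) were called in CCD, and 104 of them swung more than 2-fold. The CCD count was 245 and 242 without replicate 1 or replicate 2 of CCD ZT8, 278 and 297 without either replicate of CCD ZT12, and 292 without CCD ZT16 replicate 1. It was between 132 and 255 when 1 of the 6 times was left out, 117 with the F test over group means, 456 with CCD fitted alone, 702 with trend and robust options and 846 with array weights.

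Between the segments the course over the day differed in 2 genes. Ranbp3l, whose product is related to a nuclear transport cofactor, peaked at ZT 8.63 in DCT/CNT (amplitude 1.10, SE 0.14) and at ZT 17.5 in CCD (amplitude 0.99, SE 0.14), and the difference had adjusted p = 0.0005. A second Ranbp3l probe set peaked at ZT 7.12 and ZT 17.4. E230013L22Rik, an uncharacterised gene named after its values were seen, had an amplitude of 0.08 (SE 0.05) in DCT/CNT and 0.41 (SE 0.05, peak ZT 21) in CCD, with adjusted p = 0.00778 for the difference. The unadjusted p was under 0.05 in 1617 genes. The difference of Ranbp3l did not pass without ZT8 (adjusted p = 0.095), nor that of E230013L22Rik without ZT0, ZT12 or ZT20 (adjusted p up to 0.347). The count was 1 gene after quantile normalisation and 6 with the lower 50% of genes left out.

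**Figure D3:**
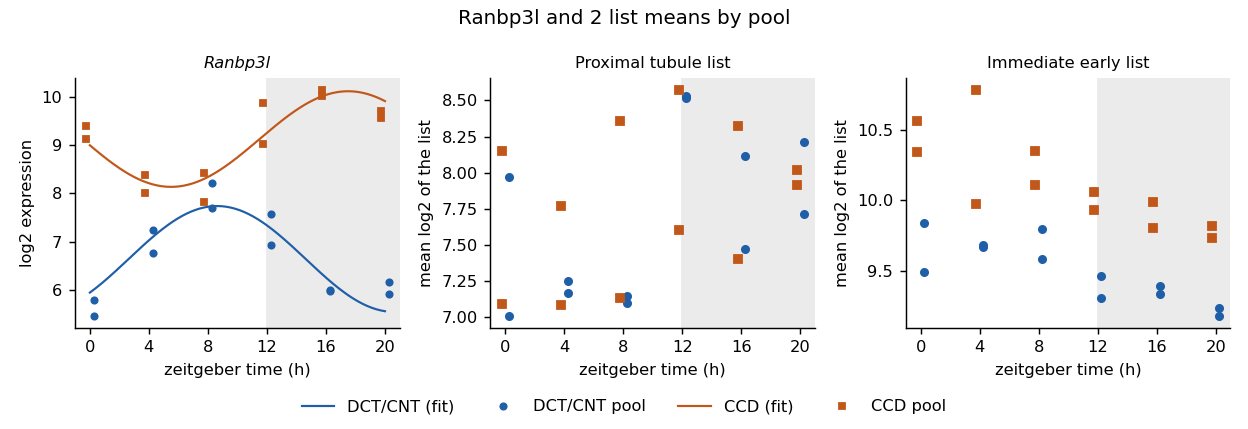
Log2 expression of Ranbp3l and the means of the proximal tubule and immediate early response lists against zeitgeber time in hours, with 1 point per pool (2 per segment and time) and fitted curves for Ranbp3l. Ranbp3l peaks at ZT 8.63 in DCT/CNT and ZT 17.5 in CCD.

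Calls in 1 segment alone were common without such a difference. Of the called genes, 237 were called in both segments, where independent lists would share 29.5. Both tests use the same variance per gene, so the lists are not independent and 29.5 is not a chance level for this fit. A further 958 were called in DCT/CNT alone and 212 in CCD alone. The fitted peaks of 697 and 166 of these lay within 4 h of each other in the 2 segments. Slc8a1 had amplitudes of 0.52 in DCT/CNT and 0.08 in CCD, and the difference did not pass (adjusted p = 0.456). Rasl11a had amplitudes of 0.59 and 1.39, and Scel, a cornified-envelope protein gene, 0.16 and 0.76, with adjusted p of 0.415 and 0.16 for the difference. The shared count was 93 with each segment fitted alone and 77 with the F test over group means. It was 147 and 141 without either replicate of CCD ZT8, and between 82 and 146 without 1 of the 6 times.

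Shared rhythmic genes kept close peak times in the 2 segments. Dbp peaked at ZT 10.5 and ZT 9.95, Cry1 at ZT 19.7 and ZT 18.7, Per2 at ZT 15.6 and ZT 15, and Nfil3 at ZT 22.3 and ZT 22.2, in DCT/CNT and CCD in that order. Over the 237 genes the circular mean of CCD minus DCT/CNT peak time was -0.272 h (SD 1.74 h over genes, which are not independent replicates), and the median absolute difference was 0.951 h. The mean ranged from -0.505 to -0.218 h when 1 array was left out and was -0.696 h without ZT0. The peaks of 193 genes lay within 2 h of each other, and those of 2 genes more than 6 h apart.

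**Figure D4:**
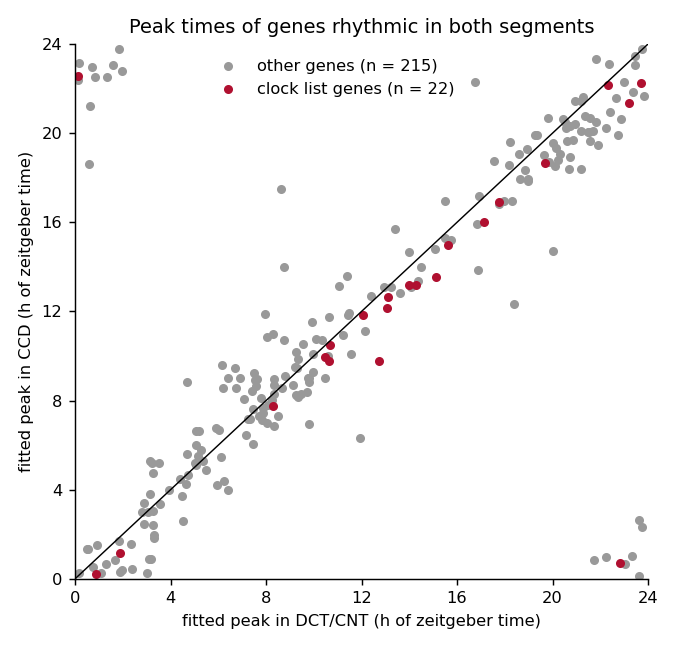
Fitted peak time in CCD against fitted peak time in DCT/CNT, both in hours of zeitgeber time, for the 237 genes called rhythmic in both segments, with clock list genes in red and the line of equal peaks. Peaks of 193 genes lie within 2 h of each other; points in the upper left and lower right corners are near the line across midnight of the scale.

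Slc12a3 was 49.2-fold higher in DCT/CNT (log2 difference 5.62, SE 0.35, adjusted p = 1.26e-09), and Pvalb, the calcium-binding parvalbumin of the DCT, 12.2-fold higher (3.61, SE 0.39). The homeobox genes Hoxc10 (22.5-fold; log2 difference 4.49, SE 0.17) and Hoxa9 (14.6-fold; 3.86, SE 0.11), the transcription factor gene Sall1 (11.5-fold; 3.52, SE 0.13), Abca13 (18.9-fold) and Cyp2j11 (17.1-fold) were also higher in DCT/CNT. In CCD the retinal dehydrogenase gene Aldh1a1 was 16.5-fold higher (log2 difference -4.04, SE 0.17), Lcn2, which encodes lipocalin 2, 14.6-fold (-3.86, SE 0.12), the transcription factor gene Elf5 11.6-fold (-3.54, SE 0.09) and the water channel gene Aqp4 10.1-fold (-3.34, SE 0.10). The rule that picked these genes required all 12 arrays of the higher segment to lie above all 12 arrays of the other. Among all called genes 5056 met this, so it does not set the named genes apart. In the lower segment Slc12a3 and Pvalb averaged 5.28 and 4.77, and Hoxc10, Sall1, Abca13, Cyp2j11, Aldh1a1 and Lcn2 also lay below the array median. Such levels were not tested against background, which can limit the folds.

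**Figure D5:**
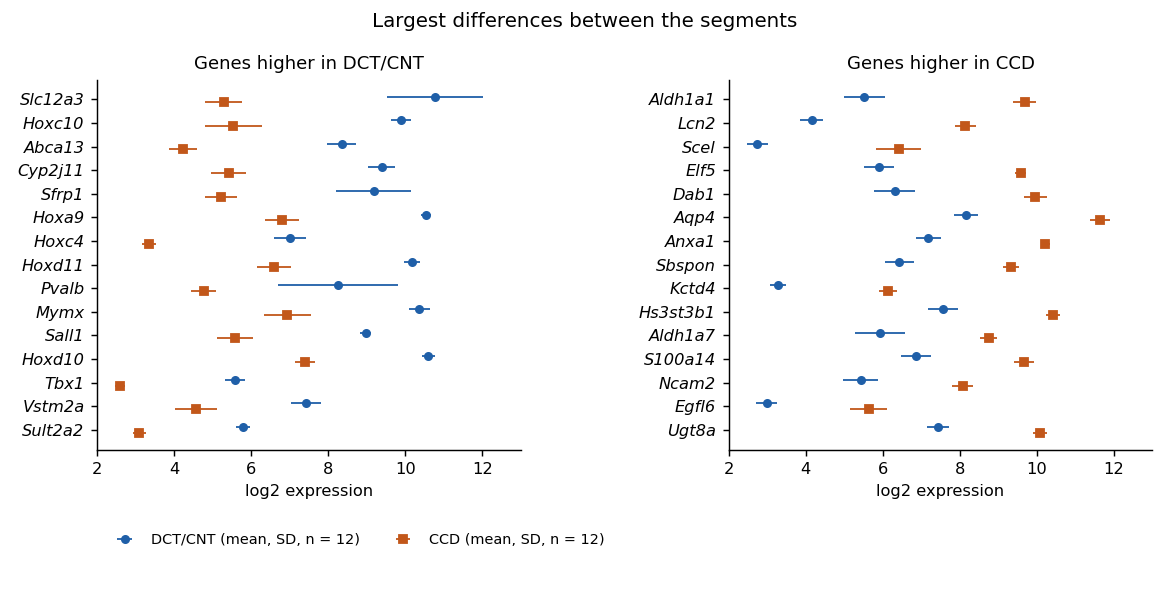
Log2 expression (mean and SD of 12 arrays) in DCT/CNT and CCD of the 15 genes with the largest differences each way. Slc12a3 leads those higher in DCT/CNT and Aldh1a1 those higher in CCD.

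Segment markers separated the tissues. Of 19 DCT and CNT markers 16 were higher in DCT/CNT and 3 in CCD (16 and 1 after quantile normalisation), with Slc8a1 6.18-fold (log2 difference 2.63, SE 0.11), Kl 4.03-fold (2.01, SE 0.06) and S100g, a calcium-binding protein gene, 3.06-fold (1.61, SE 0.07) higher in DCT/CNT. The list was higher in DCT/CNT (adjusted p = 1.22e-05; adjusted p = 0.42 with an estimated correlation). Of 19 water transport genes 13 were higher in CCD and 3 in DCT/CNT (10 and 4 after quantile normalisation), with Aqp2 4.49-fold (-2.17, SE 0.05) and Avpr2 3.03-fold (-1.60, SE 0.05) higher in CCD. That list was higher in CCD (adjusted p = 0.0289; adjusted p = 0.42 with an estimated correlation). Of 17 principal cell genes 13 were higher in CCD and 2 in DCT/CNT, and of 19 intercalated cell genes 15 and 2. Their list calls (adjusted p = 0.041 and 0.0203; adjusted p = 0.42 with an estimated correlation) ended after quantile normalisation (adjusted p = 0.312 and 0.218), where the counts were 6 and 4, and 10 and 3. Aqp6, a channel of intercalated cells, was 2.27-fold higher in CCD (-1.18, SE 0.05), and the kinase gene Sgk1 1.69-fold (-0.76, SE 0.06).

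Of the immediate early response list 14 of 20 genes were higher in CCD and 1 in DCT/CNT (12 and 4 after quantile normalisation), with Myc 2.72-fold (-1.44, SE 0.07) and Ier2 2.43-fold (-1.28, SE 0.07) higher in CCD (list adjusted p = 0.0203; adjusted p = 0.509 with an estimated correlation). Of the heat shock list 18 of 19 were higher in CCD and 0 in DCT/CNT in the deposited values, against 8 and 5 after quantile normalisation, with Hspa1a 1.94-fold higher in CCD (-0.95, SE 0.07). The heat shock and ribosomal protein lists were lower in DCT/CNT (adjusted p = 0.00548 and 0.0179; adjusted p = 0.42 with an estimated correlation for each), and neither held after quantile normalisation (adjusted p = 0.301 and 0.272). Ribosomal protein genes were higher in CCD in 17 of 24 and in DCT/CNT in 1 (10 and 5 after quantile normalisation). The unfolded protein response list (16 of 20 higher in CCD, 0 in DCT/CNT; adjusted p = 0.041; adjusted p = 0.509 with an estimated correlation) had 5 higher in CCD and 9 in DCT/CNT after quantile normalisation, where it did not pass and its mean turned to 0.0923 (adjusted p = 0.524). Markers of other cell types differed as well. The vascular list had 9 of 13 genes higher in DCT/CNT and 2 in CCD (10 and 2 after quantile normalisation), with the smooth muscle gene Myh11 3.87-fold higher (1.95, SE 0.11) and list adjusted p = 0.0203 (adjusted p = 0.42 with an estimated correlation). The thick ascending limb list had 6 of 10 higher in DCT/CNT and 1 in CCD (7 and 2 after quantile normalisation), with list adjusted p = 0.0289 (adjusted p = 0.42 with an estimated correlation and 0.194 after quantile normalisation).

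In the other lists, given as genes higher in DCT/CNT and then in CCD, the deposited values gave 2 and 12 of 16 core clock genes, 4 and 8 of 12 clock output genes, 4 and 11 of 18 glucocorticoid response genes, and 5 and 8 of 17 xenobiotic genes. They gave 1 and 6 of 19 proximal tubule, 4 and 1 of 7 podocyte, 3 and 3 of 12 endothelial, 5 and 1 of 15 leukocyte and 2 and 1 of 5 erythrocyte genes, and 0 and 1 of the 1 cold-inducible gene. They gave 2 and 14 of 20 S phase, 4 and 2 of 19 mitosis, 4 and 16 of 33 oxidative phosphorylation, 4 and 11 of 20 fatty acid oxidation and 1 and 11 of 14 cholesterol synthesis genes. None of these lists tested with camera passed in the deposited values. The proximal tubule list had a mean of -0.10 and a median of -0.05 with a camera direction towards DCT/CNT, and the endothelial list a mean of 0.08 and a median of -0.02. After quantile normalisation the oxidative phosphorylation genes split 22 and 4, the fatty acid oxidation genes 12 and 1, the cholesterol synthesis genes 4 and 1, the endothelial genes 8 and 0, and the core clock genes 4 and 11, in the same order. The clock output genes then split 5 and 2, the glucocorticoid response genes 8 and 4, the xenobiotic genes 4 and 8, the S phase genes 2 and 6, the mitosis genes 9 and 2, the leukocyte genes 8 and 1, the proximal tubule genes 2 and 1, the podocyte genes 2 and 2, the erythrocyte genes 1 and 0 and the cold-inducible gene 0 and 1. Cry2 was 2.20-fold higher in CCD (-1.14, SE 0.07) and Hlf 2.24-fold higher in DCT/CNT (1.17, SE 0.09).

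Across all genes, limma called 5522 higher in DCT/CNT and 8553 higher in CCD (77.4% of genes). The balance between the directions depended on the scaling, with 7966 and 6044 after equal medians, 6541 and 5394 after quantile and 6532 and 5483 after cyclic loess normalisation. The counts were 717 and 6986 when the lower 50% of mean values was left out, and 2348 and 5205 with proximal tubule and thick ascending limb covariates, an alternative added after the data were seen.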

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

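The tests of the patterns below were chosen before the result that each measures was seen, with 2 exceptions. The alternative with 2 covariates was chosen after the data were seen. So was the test on the 7 genes whose pool differences had r under 0.5 with the proximal tubule list.

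Ranbp3l and E230013L22Rik stood out because their rhythm differed between DCT/CNT and CCD over all genes, with adjusted p of 0.0005 and 0.00778. In 100 regroupings of the arrays within each time, after the segment means were taken out, only the real grouping gave as many as 2 genes (1 of 100). The highest other count was 1. This does not exclude chance for the count of 2 or for each gene, since the counts are close and the regroupings mix the segments within a time. The count fell to 1 after quantile normalisation and without ZT0, ZT8, ZT12 or ZT20. Adjusted over their list alone, the rhythm also differed for 6 list genes, which did not pass over all genes. Trpm6, a magnesium channel gene, gave 0.0479, with peaks at ZT 20.4 in DCT/CNT (amplitude 0.59) and ZT 4.86 in CCD (amplitude 0.20). Wnk1 gave 0.039, with peaks at ZT 18.6 and ZT 11.1. Calb1, the gene of calbindin, gave 0.0263, with peaks at ZT 20 and ZT 14.7. Mt1, a metallothionein gene, gave 0.0175, with peaks at ZT 11.9 and ZT 6.30, but those of its other probe set were at ZT 10.8 and ZT 9.85. Echs1 gave 0.0468, with amplitudes of 0.06 and 0.22. Ppara gave 0.0167, with peaks at ZT 21.8 and ZT 13.6, but those of its other probe sets lay closer (ZT 17.9 and ZT 19.6, and ZT 15.3 and ZT 12.7), and neither segment's rhythm passed over all genes (adjusted p = 0.128 and 0.0617).

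The rhythm counts were set against other orders of the times. Of the 60 distinct orders of the 6 times, 1, the real one, gave as many as 1195 genes in DCT/CNT, and the highest other count was 651. In CCD, 1 of 60 gave as many as 449, and the highest other count was 178. The share of 1 in 60 is the smallest that these orders can give. It speaks against chance for the counts as a whole, not for each gene, since other orders still called up to 651 and 178 genes. The count of genes that differ between the segments was 14075 for the real grouping and at most 10942 in the other 99 of 100 regroupings within times, so 1 of 100 gave as many. Regroupings that exchange arrays at only some of the times keep part of the segment difference by construction.

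Sphk2 carried a daily swing in both segments almost as large as that of Dbp. In the reference gene table (GRCm38.p6) Dbp overlaps Sphk2. The brighter Sphk2 probe set peaked within 0.101 h of Dbp in both segments, while the other Sphk2 probe set had an amplitude of at most 0.158 log2 units. These values are consistent with the brighter probe set measuring Dbp transcripts. A rhythm of a Sphk2 transcript that the other probe set misses stays open.

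Large-amplitude genes outside the clock lists in DCT/CNT may reflect proximal tubule cells whose share in the pools varied with time. Of the 10 such genes, 30.0% followed the proximal tubule list mean with r of 0.5 or more, against 6.2% of all genes. This r was taken over the 12 within-time differences between pools, of both segments together. It was 0.925 for Pck1, with Pck1 left out of the list mean, 0.888 for Ak4 and 0.864 for Keg1. Over the DCT/CNT arrays, where r includes the course over time, it was 0.903, 0.872 and 0.936 for these genes. There it was 0.719 for Ugt2b34, whose pool differences gave 0.12, and -0.176 to 0.207 for the rest. With the list mean as a covariate the amplitude of Pck1 went from 1.10 to 0.49, that of Keg1 from 1.06 to 0.45 and that of Ak4 from 1.07 to 0.63. Pck1 and Keg1 lost the call (adjusted p = 0.105 and 0.119) as their amplitudes shrank. The covariate includes Pck1 itself, so part of the decrease of Pck1 follows by construction. Of the 7 genes with r under 0.5, 6 stayed called with the covariate (adjusted p up to 0.0148). Their amplitudes before and after were 2.21 and 2.19 (Sphk2), 1.36 and 1.53 (Tspyl3), 1.10 and 1.08 (Ranbp3l), 1.02 and 0.99 (Zbtb16), 0.98 and 1.07 (Rnf125) and 0.98 and 0.99 (Grem1). These genes were picked by a low r with the same list mean, which limits how far the covariate can change their amplitudes. The kept calls therefore cannot decide whether a changing share of proximal tubule contributes to these 6. Ugt2b34 lost the call (adjusted p = 0.137; amplitude 1.31 before and 1.05 after), and for it, Pck1, Keg1 and Ak4 such a share and a rhythm within DCT/CNT cannot be told apart, since the amplitude shrank without vanishing and Ak4 kept its call (adjusted p = 0.00373). The clock genes were not picked by their r with the list. Of the 22 clock list genes called in both segments, 20 stayed called in both with the covariate. This argues against a changing share of proximal tubule as the sole source of those calls. Whether it adds to their amplitudes stays open.

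The segment difference might come from the narrower spread of values on DCT/CNT arrays. Quantile normalisation, which gives all arrays 1 distribution, left 11935 genes different, against 14075 in the deposited values. This argues against the spread alone as the whole cause of the differences. It does not test whether the segments were normalised in separate runs, which the labels leave open, since rescaling finished values cannot undo other effects of such runs. The excess of genes higher in CCD is another matter, since 60.8% of called genes were higher in CCD in the deposited values and 45.2% after quantile normalisation. The direction of that excess is therefore consistent with the scaling of the arrays, and a real difference in RNA composition between the segments stays open as an untested explanation.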

How the results depend on the processing

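The alternatives were chosen before the data were examined, except for the 2 covariates together and the gene lists after quantile normalisation, which were chosen after the data were seen. The peak time difference kept its sign under every alternative run, and single-array omissions gave -0.505 to -0.218 h, while it was -0.696 h without ZT0 and -0.576 h without ZT8. Below, counts are given in the order DCT/CNT rhythm, CCD rhythm and shared rhythm unless named. The cause of the changes was not tested, except that a stricter threshold calls fewer genes by construction. The main fit shares 1 variance per gene between the segments, while the median SD between pools was 0.186 in DCT/CNT and 0.157 in CCD. Thresholds of 0.1 and 0.01 gave 2303, 755 and 408, and 326, 124 and 79. The F test over group means gave 450, 117 and 77. Omitting ZT0 gave 659, 156 and 87, omitting ZT4 565, 180 and 113, omitting ZT8 745, 132 and 82, omitting ZT12 594, 181 and 91, omitting ZT16 676, 221 and 117, and omitting ZT20 788, 255 and 146. Omitting 1 array gave 818 to 1329, 242 to 477 and 141 to 235. Separate fits gave 226 in DCT/CNT, 456 in CCD and 93 shared, and array weights 788 in DCT/CNT and 846 in CCD. Each of these turns the order of the segments, which thus depends on how the variance is modelled. Trend and robust options gave 702 in CCD and 373 shared, the filter on the lower 50% 381 shared, and the 2 covariates 663 in DCT/CNT and 157 shared. The rhythm difference held in 1 gene after quantile normalisation and without ZT0, ZT8, ZT12 or ZT20, in 6 with the filter, in 4 with the mean of probe sets or with trend and robust options, in 5 at a threshold of 0.1, and in 2 to 4 when 1 array was left out. Genes higher in CCD numbered 5394 after quantile and 5483 after loess normalisation. With the filter 717 genes were higher in DCT/CNT, and with the 2 covariates 2348 were higher in DCT/CNT and 5205 in CCD. Same-number pool differences of the 2 segments correlated with r from -0.025 to 0.086 across genes. Such low values do not show a pairing by pool number, but they cannot exclude that same-number pools share animals. With a pool block the counts were 1053, 368 and 198.

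Omissions were run for genes named by the fixed rule and for the rhythm differences, not for every value of a named gene. Of the called rhythms so run, 44 of 54 in DCT/CNT and 27 of 41 in CCD held in every omission of 1 array, and 27 and 19 in every omission of 1 time. All 39 called segment differences so run held in every omission of 1 array. Some directions reversed after quantile normalisation. For DCT/CNT minus CCD, the mean of the oxidative phosphorylation list became 0.16 (adjusted p = 0.0145), that of the fatty acid oxidation list 0.20 (adjusted p = 0.0278) and that of the unfolded protein response list 0.0923 (adjusted p = 0.524), all at the preset correlation, since an estimated one was not run on these values, while Echs1 became 0.15 after quantile and 0.16 after loess normalisation. Among genes not called, the fitted curve turned for Csnk1d (-0.00968 in CCD with the mean of probe sets, and in DCT/CNT -0.00776 with the 2 covariates and -0.00615 without ZT12), Csnk1e (-0.000534 in DCT/CNT with the proximal tubule covariate and -0.0613 in CCD without ZT12) and Bhlhe41 (in DCT/CNT -0.00688 with the 2 covariates and -0.0186 without ZT8), given as amplitudes along the direction first fitted.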

Other observations

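The paragraph on homeobox genes was chosen after the values were seen, while the test of the clock phase was chosen before its result was seen.

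Homeobox genes of the Hox clusters, which pattern the body axis in development, were looked at by cluster, without a test between the clusters. As background, collecting ducts arise from the ureteric bud, and distal tubules from the metanephric mesenchyme. Of the 33 measured Hox genes, 22 were higher in DCT/CNT and 11 in CCD in the deposited values, beside 77.4% of all genes called different, and 20 and 7 after quantile normalisation. In the A cluster 9 of 9 genes were higher in DCT/CNT (7 and 0 in CCD after quantile normalisation, where Hoxa4 and Hoxa13 changed sign without passing the test), and in the C cluster 7 of 7 (7 after quantile normalisation). In the B cluster 7 of 9 were higher in CCD and 2 in DCT/CNT (5 and 2 after quantile normalisation). In the D cluster 4 of 8 were higher each way (4 in DCT/CNT and 2 in CCD after quantile normalisation, where Hoxd8 and Hoxd9 changed sign). Hoxc10 (log2 difference 4.49, SE 0.17), Hoxa9 (3.86, SE 0.11), Hoxc4 (3.79, SE 0.10) and Hoxd11 (3.70, SE 0.13) were highest in DCT/CNT relative to the median gene. Hoxb9 (-1.32, SE 0.10), Hoxd3 (-1.18, SE 0.08) and Hoxb2 (-1.12, SE 0.07) were highest in CCD. In the A, B, C and D clusters 4, 1, 3 and 3 of the counted genes lay below the mean array median in both segments. Hoxc4 and Hoxc10 did so in CCD (3.34 and 5.53) and Hoxb2 in DCT/CNT (5.35), where signal was not tested against background.

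A hypothesis was that the clock runs slightly ahead in CCD. Of the 22 clock list genes called in both segments, 21 had an earlier fitted peak in CCD, with a mean of -0.835 h (SD 0.884 h over genes). Over all 237 genes called in both the mean was -0.272 h, and 91 had a later fitted peak in CCD. When the segment labels were exchanged by time, 2 of the 64 exchanges, the real one and its mirror, gave a mean as far from 0, and the largest of the others was 0.78 h (exact permutation p = 0.0312, two-sided, the smallest they can give). The values are consistent with an earlier clock phase in CCD by less than the 4 h between samples. A later dissection of one segment than of the other within each session could give such a shift too, and the labels do not state the order.

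A 12 h component beside the 24 h one was called by limma in 2 genes in DCT/CNT, Cryzl1 (adjusted p = 0.0167) and Mageh1 (adjusted p = 0.00908), which were named after their values were seen. In CCD it was called in 0 genes, with an unadjusted p under 0.05 in 636.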
